A study of Homo sapiens with 8 samples.

How the data were processed

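Open chromatin was measured by ATAC-seq, in which the Tn5 transposase cuts and tags accessible DNA, in 8 libraries from 2 B cell precursor acute lymphoblastic leukaemia lines. Each line gave 2 libraries from cells with an empty guide vector and 2 libraries from 1 clone edited at SETD2, clone BM_B in 697 and clone BA in KOPN-8, which the labels describe as heterozygous. The labels call the libraries of a group biological replicates and do not say how the cultures were separated, so the spread between them may be partly technical. All libraries of a knockout group came from the same clone, so a difference between a clone and its control line holds any difference between 1 clone and a bulk population together with the effect of the edit.

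Reads were aligned with Bowtie2 to hg19 and peaks were called with MACS2, per the submitters' processing notes. Their versions and settings, the treatment of duplicate reads and the shift applied to transposase cut sites are not given in the sources used here. The lists hold 1 set of peaks per library, so calls had not been pooled over replicates. Each deposited list gives a peak's chromosome, start, end, name and 1 value. The deposited value was read as a fold enrichment, a linear ratio of the peak's pileup to the local background, because its low values lie on an even grid. This value is the authors' own and was used only to rank or filter peaks within a list. The numbers in the peak names have gaps, and between 0.946% and 1.04% of the numbers in a list are missing. A filter that is not described in the labels had therefore removed a few peaks after calling. All peaks were at least 200 bp wide.

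The lists held between 57154 and 76495 peaks. Read depth is unknown. Under the caller's usual formula with a pseudocount of 1, the grid step of the fold values gives a background pileup between 2.51 and 3.49. With the settings not given, it cannot be turned into a read depth. In each group the list with the higher background pileup was also the longer one, and whether depth set both was not tested. Positions are given in hg19, counted from 1.

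The 4 lists of a line were merged into regions wherever peaks shared at least 1 bp, and a library called a region where it had a peak in it. A region was counted as gained when both knockout libraries called it and neither control did, and as lost in the opposite case. The same count was made for the other 2 ways of dividing the 4 libraries into pairs. Chromosomes were compared with two-sided Fisher's exact tests of gained against lost regions and of changed against all other regions, with Benjamini-Hochberg adjustment over 24 chromosomes and a threshold of 0.05. Ratios of gained to lost regions have 0.5 added to each count. Regions are not independent replicates, so these tests compare the 4 libraries at hand. For the comparison of both lines the 8 lists were merged together. Numbers of peaks were compared by exact permutation of library labels within each line. With 2 libraries against 2 the smallest two-sided p is 0.333, and over both lines it is 0.0556, so no test of libraries could pass the threshold. List similarity was the Jaccard index of covered bases. Shares of peaks were also taken in windows of 10 Mb and 2 Mb by peak start, and windows of 10 Mb with fewer than 60 regions were not described.

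Regions are named by a rule set before the data were examined: per line and direction, the 10 with the highest smaller percentile of the fold within the 2 lists that call them, and the 10 changed the same way in both lines by the same order. No gene annotation in hg19 was used, so the planned tests of promoters and gene bodies, the planned tests of 15 gene lists and the naming of genes near regions were not run. For the same reason peaks at SETD2 itself, which the RefSeq gene table for GRCh38 places on chromosome 3, were not analysed here, and the edit was not checked. That table was used otherwise only to count protein-coding genes per chromosome.

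Alternatives chosen before the data were examined were the strongest 50% of each list, lists cut to equal length (57154 peaks for 697 and for all 8 lists, 63585 for KOPN-8), calls that cover at least 50% of a region, peaks of replicates sharing at least 50% of both, a minimum width of 200 bp, each library left out and a replicate block. Counts of strong calls, counts and chromosome tests without the chromosomes that stood apart, the direction test in both lines under other settings, the segments of chromosomes, the runs of neighbouring regions and the comparison of the strongest 10000 peaks of each list were chosen after seeing the data. The calling code was checked on simulated lists with 200 gained and 400 lost regions planted. All 200 and all 400 were recovered for the simulated design of 697, among 303 gained and 506 lost calls over 50313 regions, and all for that of KOPN-8, among 320 and 530 calls over 61461 regions. Planted regions were exempt from the random loss of peaks and lay apart from their neighbours, so their full recovery was fixed in advance. The rate of random loss was set by hand and not taken from these lists. The simulation therefore checks the code and gives no sensitivity or rate of false calls for these data. The merged regions were checked against bedtools. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1 were used.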

Results

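ATAC-seq peak lists were compared between cells carrying an empty guide vector and SETD2 heterozygous knockout clones in 697 and KOPN-8. SETD2 is a histone H3 lysine methyltransferase that acts along transcribed genes. 697 and KOPN-8 are established B cell precursor leukaemia lines. Each of the 4 groups had 2 libraries. Control lists of 697 held 57154 and 70099 peaks and those of the 697 clone 63012 and 76495. Control lists of KOPN-8 held 70430 and 63585 peaks and those of its clone 67301 and 64667. The mean was 63627 ± 9154 (SD, n = 2) against 69754 ± 9534 in 697 and 67008 ± 4840 against 65984 ± 1863 in KOPN-8. The difference between arms was smaller than the SD of either group in both lines (exact permutation, two-sided p = 0.667 in 697 with n = 2 per group, p = 1 in KOPN-8, p = 0.556 over both lines). The median peak was wider in the clones, at 322 and 327 bp against 314 and 317 bp in 697 and at 331 and 329 bp against 326 and 327 bp in KOPN-8 (exact permutation over both lines, p = 0.0556, the smallest that 2 against 2 libraries in each line can give).

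Duplicates resembled each other more than they resembled the other arm, clearly in KOPN-8 and by a small margin in 697. In 697 the Jaccard index of covered bases was 0.618 and 0.633 within groups and 0.602 ± 0.0205 (SD) over the 4 control-knockout pairs, 3 of which, at 0.615, 0.613 and 0.61, lay close to the lower duplicate pair and 1, control 1 with knockout 2, at 0.572. With equal list lengths the 697 control duplicates, at 0.644, lay below control 2 with either knockout, at 0.651 and 0.66. In KOPN-8 it was 0.663 and 0.682 within groups and 0.635 ± 0.00409 over the 4 control-knockout pairs, all of which lay below both duplicate pairs. Lists of different lines had an index of 0.408 ± 0.0108 over 16 pairs. The difference between the lines was thus far larger than that between a clone and its control.

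The first comparison asked which regions were called in the 697 clone and not in its controls, or the reverse. The 4 lists merged into 96698 regions, of which 42665 (44.1%) were called in all 4 libraries. The clone gained 4186 regions (4.33%) and lost 1772 (1.83%). Gained regions were weak within their lists, with a median percentile of 28.3 and a median width of 304 bp, while regions called in all 4 libraries had a median percentile of 67.3 and a median width of 545 bp. Lost regions had a median percentile of 22.1. Dividing the libraries by replicate number instead gave 4045 regions called only in the replicates 2 and 399 only in the replicates 1, and the crossed division gave 1279 and 1182. The 697 total of 5958 changed regions therefore lay above the 4444 and 2461 of the other divisions. Even so, the number gained was close to the 4045 called only in the replicates 2, whose lists were longer in both arms. With lists cut to equal length the clone gained 2948 and lost 2127 regions, and when only peaks in the strongest 50% of their list counted as a gain or loss, 223 were gained and 97 lost. Leaving out 1 library loosens the rule, and the count of gained regions then ranged from 5603 without control 1 to 17206 without knockout 1 and that of lost regions from 2489 without knockout 1 to 10977 without control 1. Because all knockout libraries of a line came from 1 clone, differences of that clone and effects of the edit were not separated.

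**Figure D1:**
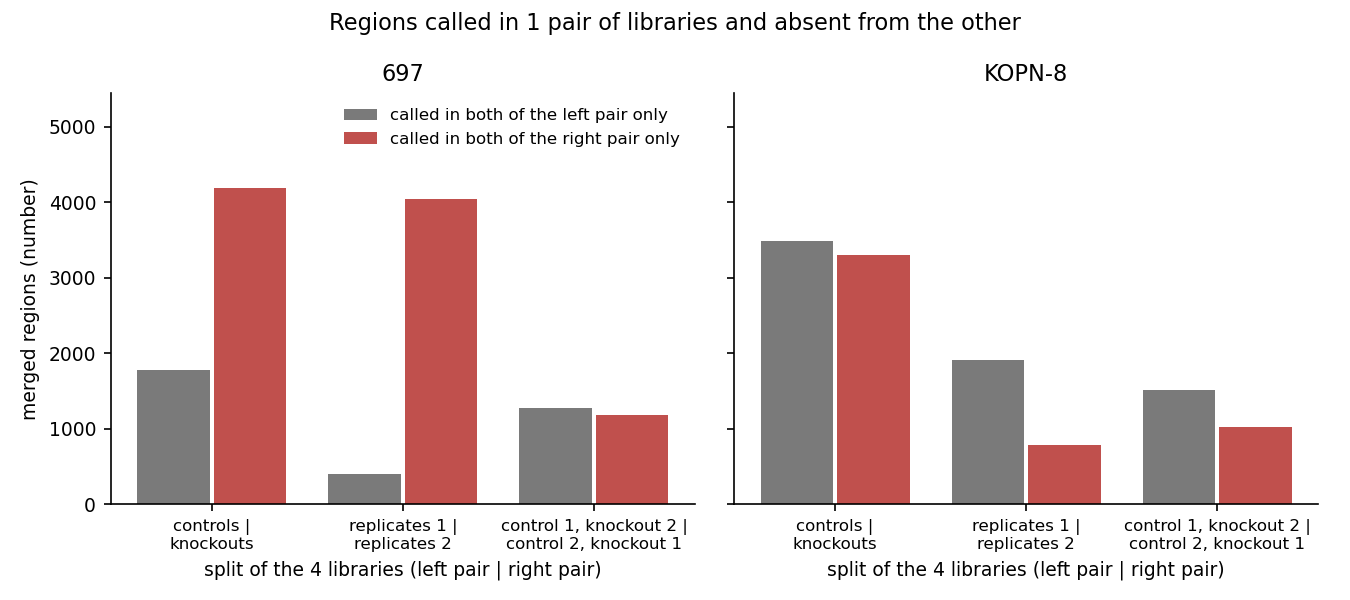
Number of merged regions called in both libraries of 1 pair and in neither of the other, for the 3 ways of dividing the 4 libraries of each line. In 697 the division by arm gave 1772 regions for the controls and 4186 for the knockouts, and in KOPN-8 it gave 3488 and 3308, more in total than either other division.

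Of all chromosomes, 19 had the highest percentage of its own regions gained in the 697 clone. Of its 1618 regions 193 (11.9%) were gained and 2 (0.124%) were lost, against 4.20% gained and 1.86% lost on the other chromosomes. The log2 ratio of gained to lost regions was 6.27 there and 1.17 elsewhere (Fisher's exact test, adjusted p = 2.1e-26). Relative to the other chromosomes this log2 ratio was 5.10, and without knockout 2 it fell to 2.96. Chromosome 19 took 1.51 ± 0.0722% (SD, n = 2) of all peaks in the controls and 2.0 ± 0.0156% in the clone. Among the strongest 10000 peaks of each list, 44 and 44 lay on chromosome 19 in the controls and 142 and 184 in the clone. In the 697 controls only chromosomes 22 (31 and 35) and Y (14 and 17) held fewer of these peaks. Chromosome 13, with 2.94 protein-coding genes per Mb against 24.6 on chromosome 19, held 245 and 244. The KOPN-8 controls held 278 and 272 on chromosome 19. The reason for the low count in the 697 controls was not tested. The increase in the clone was found along chromosome 19 and was greatest between 20 and 30 Mb. There 37 of 100 regions were gained and the peak share was 1.88 times that of the controls, while between 50 and 60 Mb it was 1.17 times. Chromosome 22, with 66 gained and 1 lost, chromosome 20, with 77 and 7, chromosome 15, with 126 and 19, chromosome 21, with 106 and 20, and chromosome 16, with 136 and 29, also held an excess of gained regions (Fisher's exact test, adjusted p between 1.95e-08 and 0.000987).

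Chromosome Y had the highest percentage of its own regions lost in the 697 clone, although most of the 1772 losses lay elsewhere. Of 158 regions on Y, 103 (65.2%) were lost and 0 gained (Fisher's exact test, adjusted p = 1.62e-54). The control lists held 118 and 146 peaks on Y, and each knockout list held 1, at 21154525 to 21155121, a region called in all 8 libraries. Chromosome 8, with 225 gained and 159 lost, and chromosome 4, with 256 gained and 166 lost, had a lower ratio of gained to lost regions than the rest (log2 ratios 0.50 and 0.62, Fisher's exact test, adjusted p = 3.61e-06 and 4.16e-05). Most of the losses on chromosome 4 lay outside the stretch between 130 and 140 Mb, but there 21 of 144 regions were lost, 4 were gained, and the lists held 86 and 113 peaks in the controls and 47 and 65 in the clone. Between 130 and 132 Mb, over only 32 regions, the control lists held 22 and 26 peaks and the knockout lists 9 and 11, and between 134 and 136 Mb, over 44 regions, they held 21 and 38 and the knockout lists 6 and 9. In KOPN-8 the share of peaks between 130 and 140 Mb was also lower in the clone, at 0.84 times that of the controls (0.781 to 0.906 over pairs), with 11 lost and 4 gained of 224 regions. In all, 9 of 24 chromosomes passed the threshold for direction, 6 towards gained and 3 towards lost regions, and 16 passed without either control and 6 without knockout 2. Under the division by replicate number and the crossed division 0 chromosomes passed (Fisher's exact test with Benjamini-Hochberg adjustment), and 3 and 0 had an unadjusted p under 0.05. The test of changed against all other regions passed on 8 chromosomes in the division by arm, and also on 4 and 2 in these other divisions.

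The strongest regions gained in the 697 clone lay on chromosomes 2, 3, 4, 7, 15, 19 and 20. The first was on chromosome 20 from 41160158 to 41160763, with folds over background of 11.5 and 14.8 in the lists of the clone and a smaller percentile of 87.7. It was followed by chromosome 4 from 11136533 to 11136975 (percentile 86.0), chromosome 19 from 30185511 to 30185848 (82.3), chromosome 3 from 75629148 to 75629677 (82.2) and chromosome 2 from 182756255 to 182756902 (80.8). Of the 10 gained regions named by the rule 4 were on chromosome 19, the others of these starting at 28977860, 31711450 and 23692562. The remaining regions were on chromosome 15 from 23683354 to 23683727 and on chromosome 7 from 99517078 to 99517418. All 10 named lost regions were on chromosome Y, with smaller percentiles from 89.8 to 98.1, and the first lay from 16945987 to 16946384, with folds of 16.4 and 16.5 in the controls. Outside Y, chosen after the values were seen, the strongest lost regions were on chromosome 12 from 93771264 to 93771872 (percentile 88.5), chromosome 15 from 91950706 to 91951142 (84.6) and chromosome 4 from 134241752 to 134242094 (83.3).

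The second comparison asked the same of the KOPN-8 clone. The 4 lists merged into 91514 regions, of which 45054 (49.2%) were called in all 4 libraries. The clone gained 3308 regions (3.61%) and lost 3488 (3.81%), so gains and losses were nearly balanced. Gained and lost regions were again weak, with median percentiles of 25.8 and 25.7 against 65.5 for regions called in all 4 libraries. The total of 6796 changed regions was above the 2698 and 2544 that the other divisions of the libraries gave. With equal list lengths the counts were 3296 gained and 3121 lost, and 150 gained and 191 lost regions rested on peaks in the strongest 50% of their list. With 1 library left out, gained regions ranged from 4965 without control 2 to 10031 without knockout 2, and lost regions from 5641 without knockout 2 to 12008 without control 2.

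Chromosomes 8 and 13 had the highest percentages of their own regions lost in the KOPN-8 clone, although most of the 3488 losses lay elsewhere. Chromosome 8 had 74 gained and 425 lost regions of 5609 (log2 ratio -2.51 against 0.08 elsewhere, Fisher's exact test, adjusted p = 1.78e-59), and chromosome 13 had 57 gained and 226 lost of 3137 (log2 ratio -1.98, adjusted p = 5.24e-23). Chromosome 8 took 6.33 ± 0.00738% (SD, n = 2) of all peaks in the controls and 4.99 ± 0.119% in the clone, and chromosome 13 took 3.33 ± 0.0832% and 2.73 ± 0.0065%. The deficit did not cover the whole of either chromosome. On chromosome 8 the clone's share was 0.766 times that of the controls up to 130 Mb, with 405 lost regions. The share was 0.876 times between 130 and 140 Mb (0.796 to 0.957 over pairs). From 140 Mb onwards it was 1.09 times, with 7 lost and 12 gained. On chromosome 13 it was 1.05 times between 10 and 50 Mb, 0.897 times between 50 and 60 Mb and 0.703 times from 60 Mb on, where 185 of 2034 regions were lost and 16 gained. Windows of 2 Mb were uneven. The log2 ratio of shares was 0.15 between 0 and 2 Mb on chromosome 8 and -1.05 between 56 and 58 Mb on chromosome 13, over only 16 regions. The lowest 10 Mb window, between 80 and 90 Mb on chromosome 13, held 294 and 228 peaks in the controls and 141 and 144 in the clone. In the 697 clone the peak share of chromosome 8 up to 130 Mb was 0.953 times that of its controls and that of chromosome 13 from 60 Mb 0.966 times.

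**Figure D2:**
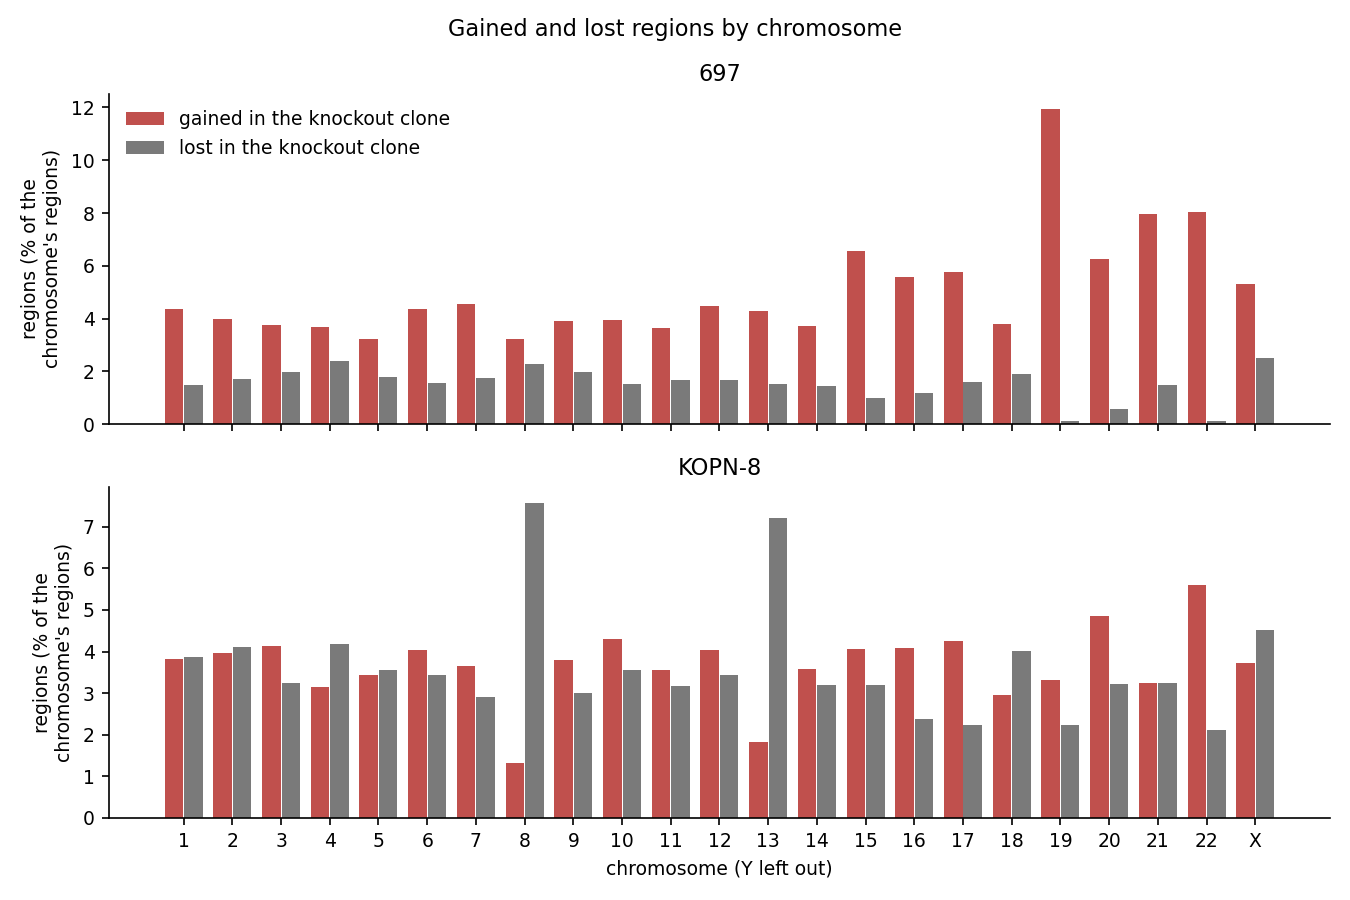
Share of each chromosome's merged regions that were gained (red) or lost (grey) in the knockout clone, in percent, for 697 above and KOPN-8 below. Chromosome 19 reached 11.9% gained in 697, and chromosomes 8 and 13 reached 7.58% and 7.20% lost in KOPN-8; Y, where 65.2% of regions were lost in 697, is not drawn.

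Of the other KOPN-8 chromosomes, 17, with 116 gained and 61 lost regions, 22, with 66 and 25, 16, with 100 and 58, 3, with 264 and 206, and 20, with 104 and 69, held more gained than lost regions (Fisher's exact test, adjusted p between 3.21e-05 and 0.00884). Chromosomes 6, 7, 9, 10 and 19 also leaned towards gained regions (Fisher's exact test, adjusted p between 0.0298 and 0.047), and chromosome 4, with 173 gained and 229 lost, towards lost ones (exact test, adjusted p = 0.047). Altogether 13 of 24 chromosomes passed the threshold, 10 towards gained and 3 towards lost regions, and 7 passed without knockout 1. Many of these leans reflected the losses on 8 and 13, which are part of the comparison. With both left out, after the data had been seen, 3177 gained and 2837 lost regions remained and 5 of 22 chromosomes passed, 16, 17 and 22 towards gained and 4 and 18 towards lost regions. The other 2 divisions of the libraries gave 2 chromosomes, 15 and 22, and 0 chromosomes (unadjusted, 3 and 5 had a p under 0.05). The test of changed against all other regions passed on 3 chromosomes in the division by arm and on 0 and 1 in the other 2.

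**Figure D3:**
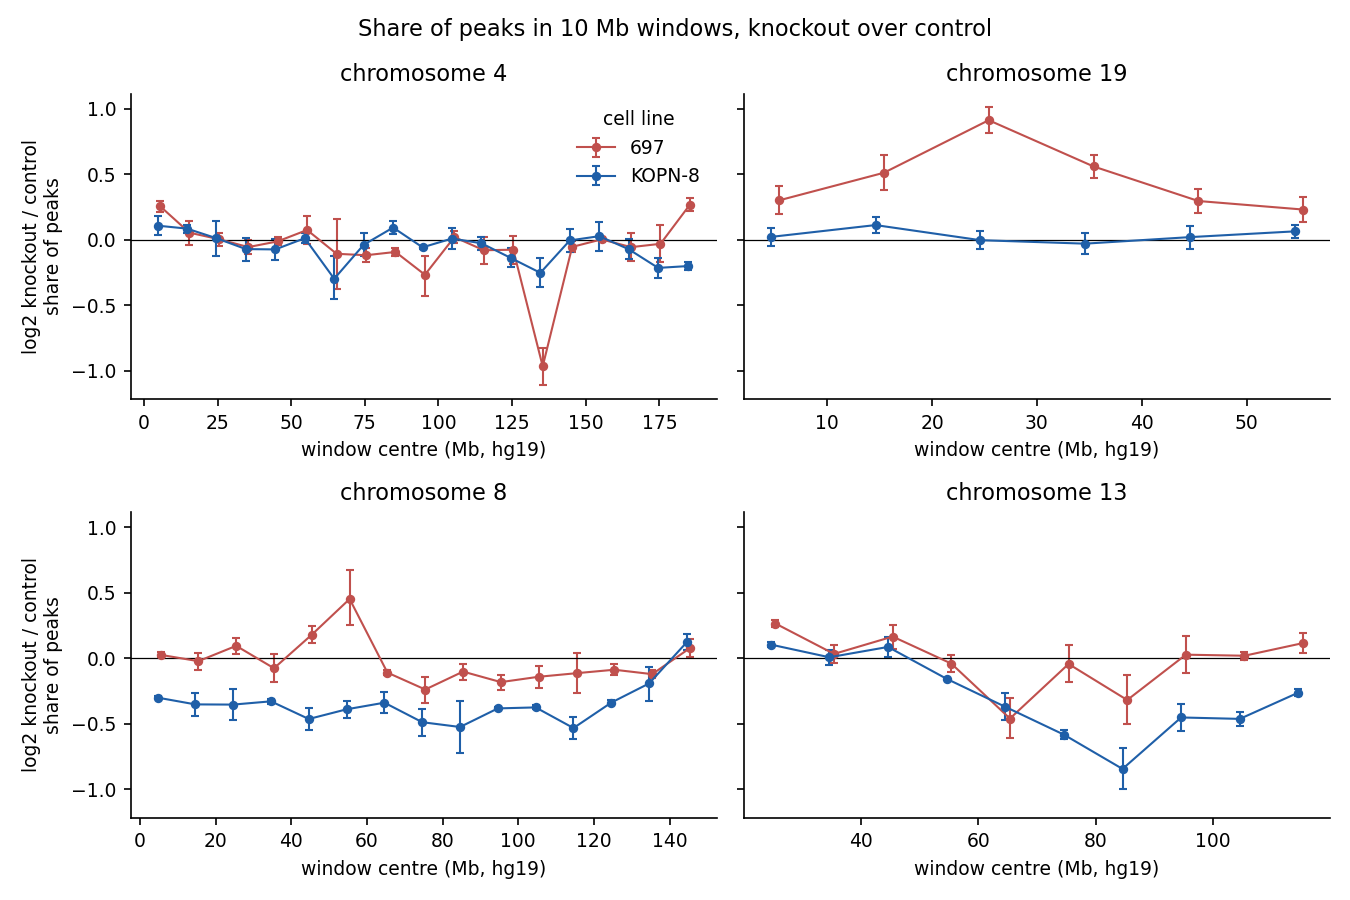
Log2 ratio of the knockout share to the control share of peaks in 10 Mb windows along chromosomes 4, 19, 8 and 13, with red for 697 and blue for KOPN-8. Points are ratios of mean shares and bars span the 4 control-knockout pairs of libraries; the lowest 697 window lies at -0.97 on chromosome 4, the highest at 0.91 on chromosome 19, and the lowest KOPN-8 window at -0.84 on chromosome 13.

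Named regions of the KOPN-8 clone were spread over the genome. The strongest gained regions were on chromosome 10 from 89264379 to 89265296, with folds of 12.7 in each list of the clone (smaller percentile 90.7), on chromosome 10 from 101418902 to 101419392 (89.0), on chromosome 6 from 6943048 to 6943523 (84.9), on chromosome 14 from 96064113 to 96064603 (84.6) and on chromosome 3 from 141943711 to 141944662 (84.2). The other gained regions of the rule were on chromosomes 2, 9, 12, 12 and 17, with percentiles down to 77.8. The strongest lost regions were on chromosome 18 from 34704442 to 34704830, with folds of 11.6 and 12.7 in the controls (88.8), on chromosome 4 from 90391002 to 90391593 (87.0), on chromosome 1 from 118679037 to 118679489 (85.1), on chromosome 9 from 16277512 to 16277895 (85.1) and on chromosome 4 from 95822376 to 95823039 (84.7). The other lost regions were on chromosomes 1, 2, 6, 10 and 21, with percentiles down to 76.3. None of the 10 was on chromosome 8 or 13.

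The third comparison asked which changes the clones of both lines shared. Over the 133028 regions of all 8 lists, 82 were gained in both lines and 39 were lost in both. With 1 library left out these counts rose to as many as 253, without 697 knockout 1, and 142, without 697 control 1. Independent lists of these lengths would share 100.3 and 45.7. Another 67 regions were gained in 697 and lost in KOPN-8, and 28 were lost in 697 and gained in KOPN-8, against 106 and 43.1. Thus 121 of the 216 regions changed in both lines (56.0%) had moved the same way (Fisher's exact test of direction, odds ratio 1.70, p = 0.0789), which did not pass the threshold. With lists of equal length 125 of 206 had moved the same way (Fisher's exact test, odds ratio 2.34, p = 0.00452), a setting added after seeing the data, while the test did not pass with calls covering 50% of a region (exact test, odds ratio 1.5, p = 0.187) or in the strongest 50% of each list (odds ratio 2.31, p = 0.0652). The other 8 pairings of divisions of the 2 lines gave between 33 and 164 regions changed in both. In either order they gave no more than 91. These divisions changed fewer regions within a line, 4444 and 2461 against 5958 in 697 and 2698 and 2544 against 6796 in KOPN-8. Fewer shared regions would follow from these totals alone, so the raw counts show no excess of sharing in the division by arm. Among regions called in at least 1 library of each line, 52547 in number, independent lists would share 48.1 gained and 15.6 lost regions, and 55.2 and 13.6 regions changed in opposite directions, so all 4 counts lay above these values.

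The regions named as changed in both lines were weak in at least 1 of the 4 lists that call them. By the rule, the first were lost regions on chromosome X from 108590491 to 108591209 (smallest percentile 44.8 of the 4 lists that call it), chromosome 17 from 69469397 to 69469675 (42.4) and chromosome 3 from 19468982 to 19469339 (41.5), and gained regions on chromosome 6 from 53495657 to 53496073 (41.2) and chromosome 10 from 23814403 to 23814658 (38.6). The other 5 were on chromosomes 8 (lost), 21, 1, 12 and 11 (gained), with percentiles down to 34.6. None of these 10 regions lay in the strongest 50% of all 4 lists that call it. Of 4102 regions gained in 697, 1119 (27.3%) were called in both KOPN-8 controls, and of 1762 lost 262 (14.9%) were, against 63.8% of the regions called in both 697 controls. In KOPN-8, 706 of 3254 gained regions (21.7%) and 865 of 3450 lost regions (25.1%) were called in both 697 controls, against 57.7% of the regions called in both KOPN-8 controls. These sets differ in strength. Gained and lost regions had median percentiles from 22.1 to 28.3, and regions called in all 4 libraries of a line 67.3 in 697 and 65.5 in KOPN-8. Regions of like strength were not compared.

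The control libraries were compared to set the difference between the lines beside that between arms. Of 109045 merged regions, 13028 were called in both 697 controls and in neither KOPN-8 control, and 17232 in both KOPN-8 controls only, while 30636 (28.1%) were called in all 4. With 1 library left out the counts rose to as many as 26689, without 697 control 1, and 27753, without KOPN-8 control 2. The other 2 divisions of these libraries gave 1105 and 1563 regions. Regions of 1 line were stronger than those of 1 arm, with 38.9% of their peaks in the strongest 50% of the list in 697 and 41.5% in KOPN-8, against 13.1% for regions gained in the 697 clone. Chromosomes 19, 20, 17 and 22 held the clearest excess of KOPN-8 regions. The share of peaks on each of these was also higher in the 697 clone than in the 697 controls (1.33, 1.12, 1.08 and 1.27 times). Both comparisons use the same 697 control libraries, so they are not independent. Chromosome 19 had 26 regions of 697 only and 655 of KOPN-8 only (Fisher's exact test, adjusted p = 3.08e-124), with 1.51 ± 0.0722% of peaks in 697 and 2.80 ± 0.0673% in KOPN-8 (SD, n = 2), chromosome 20 had 90 and 635, chromosome 17 had 114 and 675, and chromosome 22 had 42 and 280. Chromosome 2, with 1472 and 1300, and chromosome 11, with 788 and 664, had an excess of 697 regions. On chromosome Y 103 regions were of 697 only and 0 of KOPN-8 only. In total 19 of 24 chromosomes passed the threshold, 11 towards 697 and 8 towards KOPN-8.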

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

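The share of all peaks that fell on 4 chromosomes moved in opposite directions in the clones of the 2 lines, with both knockout libraries below both controls in 697 and above both controls in KOPN-8. The difference between the lines was not tested. It was looked for, as was the check that follows, after the data had been seen. The knockout share was 0.971 times the control share in 697 and 1.02 times in KOPN-8 for chromosome 3, 0.961 and 1.04 times for chromosome 9, 0.976 and 1.04 times for chromosome 10, and 0.972 and 1.02 times for chromosome 11. If the order of libraries were random and chromosomes independent, 1.33 of 24 chromosomes would move in opposite directions, in either order, and 0.667 in this order, but shares of 1 library sum to 100% and are not independent. With chromosomes 8 and 13 left out of the KOPN-8 totals and Y and 19 out of the 697 totals, the KOPN-8 ratio was 1.00 on both chromosomes 3 and 11, where the libraries of the arms then overlapped. The opposite order stayed on chromosome 9 (0.964 and 1.02) and chromosome 10 (0.979 and 1.01).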

How the results depend on the processing

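Most counts kept their size when list length, overlap or region definition changed, and the numbers of regions moved mainly with rules that make calling easier or harder by construction. Calls that cover 50% of a region, replicate peaks sharing 50% of both, and equal list lengths left all 6 counts of gained, lost and shared regions within 1.5 times, and a minimum width of 200 bp removed nothing. In the strongest 50% of each list the counts were 1869 gained and 774 lost in 697, 1827 and 2004 in KOPN-8, and 52 and 21 in both lines. Strong calls in 1 arm with no peak in the other, chosen after seeing the data, numbered 223 and 97 in 697 and 150 and 191 in KOPN-8. Leaving out 1 library loosens the rule, and each of the 8 libraries moved the gained or the lost count of its line by more than 1.5 times. Gained regions then ranged from 5603 (without control 1) to 17206 (without knockout 1) in 697 and from 4965 (without control 2) to 10031 (without knockout 2) in KOPN-8, and lost regions from 2489 (without knockout 1) to 10977 (without control 1) and from 5641 (without knockout 2) to 12008 (without control 2). Regions gained in both lines ranged from 111 (without 697 control 1) to 253 (without 697 knockout 1) and lost in both from 50 (without 697 knockout 1) to 142 (without 697 control 1). Regions of 697 controls only ranged from 14445 (without KOPN-8 control 2) to 26689 (without 697 control 1) and of KOPN-8 controls only from 18282 (without 697 control 1) to 27753 (without KOPN-8 control 2). Chromosomes past the threshold numbered 6 (without knockout 2) to 16 (without either control) in 697 and 7 (without knockout 1) to 17 (without control 2) in KOPN-8. They numbered 5 in KOPN-8 without chromosomes 8 and 13, chosen after seeing the data, because their losses lie in the comparison of every other chromosome. The directions of chromosomes Y, 19 and 22 in 697 and 8 and 13 in KOPN-8 held with equal lengths and with each library of the line left out. The sizes moved more. With 1 library left out, the log2 ratio relative to other chromosomes went from 5.10 down to 2.96 on 19 and from 4.25 to 2.19 on 22. It went from -2.59 to -1.66 on 8 and from -1.97 to -1.09 on 13. On Y it ranged from -10.5 to -7.22. With equal lengths that of 22 was 6.48. Equal lengths took the direction of regions changed in both lines past the threshold (odds ratio 2.34), while calls covering 50% and the strongest 50% (2.31) did not; the cause was not tested. Duplicates exceeded control-knockout pairs by a Jaccard index of 0.023 in 697 and 0.0372 in KOPN-8, which became 0.0415 in KOPN-8 with equal lengths, and by 0.0452 and 0.0428 as the share of the shorter list that overlaps, another scale. With the replicate block the differences were 0.014 and 0.0364. Paired by number, the counts of regions are the same by construction (4186 and 1772, 3308 and 3488, 82 and 39), and the knockout lists held 6127 more peaks in 697 and -1024 in KOPN-8, the unpaired values (exact sign-flip test over 4 pairs, p = 0.375, smallest possible 0.125). Deviations of same-numbered libraries had correlations of 0.00286 in 697 and -0.00301 in KOPN-8 over regions. In 697 both libraries numbered 2 had longer lists than those numbered 1 (70099 against 57154 and 76495 against 63012). There the number goes with a difference in list length. Of the 50 named regions all 50 kept their calls with equal lengths. In the strongest 50% the 40 of 1 line did and the 10 of both lines did not. These outcomes follow from the percentiles by which the regions were named, so they test nothing. With 50% cover, which the percentiles do not fix, 49 kept their calls. Tests of positions in genes, with both alternatives, and of gene lists, with all 3, were not run. Read depth is unknown, so what it limits was not measured.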

Other observations

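The tests in this part were chosen after the results had been seen, except that equal list lengths for chromosome 19 were planned. Shares of peaks moved alike in both clones upwards on 7 chromosomes, 1, 7, 15, 16, 17, 20 and 22. There both knockout libraries lay above both controls in each line. If order were random and chromosomes independent, 0.667 of 24 chromosomes would do so. Shares within a library have a fixed sum, however, and are not independent. On chromosome 8 both knockout libraries lay below both controls in each line, at 0.957 times in 697 and 0.789 times in KOPN-8. In both lines the log2 ratio of gained to lost regions rose with gene density. The correlation was 0.426 over 21 autosomes in 697 without 19, and 0.647 over 20 in KOPN-8 without 8 and 13. Whether the 7 follow that trend was not tested. With Y and 19 left out of the 697 totals and 8 and 13 out of the KOPN-8 totals, 4 of the 7 remained, 15, 16, 20 and 22, and the KOPN-8 ratio was 1.00 on chromosomes 1 and 7. Chromosome 22 had the largest ratio of the 7 in both lines, 1.27 in 697 and 1.11 in KOPN-8 over all peaks, and 1.27 and 1.09 with those chromosomes left out. Among the strongest 10000 peaks of each list it held 31 and 35 in the 697 controls and 46 and 75 in the clone, and 59 and 76 in the KOPN-8 controls and 98 and 83 in the clone. In the 697 clone the ratio of gained to lost regions was higher within 10 Mb of the longest stretch without peaks on each chromosome. With Y and 19 left out, 663 of 12119 regions there were gained (5.47%) and 163 lost, against 4.02% gained farther away (Fisher's exact test of gained against lost, odds ratio 1.84, p = 1.03e-11), and in KOPN-8 the odds ratio was 1.08 (p = 0.337). In 697 the percentage gained was higher near that stretch on 16 of these 22 chromosomes. Regions are not independent replicates, and the test near that stretch was not run for the other divisions of the libraries. Its p-values are therefore no measure of chance.

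Several windows and runs stood out from their chromosome. In 697 the peak share rose in every control-knockout pair between 60 and 70 Mb on chromosome X (log2 ratio 0.67, 34 gained and 2 lost of 156 regions) and between 20 and 30 Mb on chromosome 15 (0.72, 28 gained and 0 lost of 150). Runs of at least 5 regions that both libraries of 1 arm called, with no call of the other arm in between, numbered 9 in the real division and 0 in the others, and 5 of the 9 were losses on Y in 697 and on 8 and 13 in KOPN-8. In 697, 5 of 5 regions from 118440122 to 118476784 on chromosome 2 and 5 of 6 from 165535473 to 165581928 on chromosome 4 were lost. In KOPN-8, 5 of 6 from 69254512 to 69373448 on chromosome 1 were lost and 5 of 6 from 19652623 to 19790189 on chromosome 1 were gained.

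The KOPN-8 clone had fewer calls on chromosome 8 up to 130 Mb and chromosome 13 from 60 Mb. The trend with gene density over the other 20 autosomes does not reach the log2 ratios of gained to lost regions on these chromosomes. It predicted 0.08 for chromosome 8 and -0.24 for chromosome 13, against -2.51 and -1.98 observed (-7.74 and -5.20 residual SDs). Both were left out of the fit because they stood apart, so these residual SDs are no measure of chance. In 697 these segments kept 0.956 times the control share (0.932 to 0.981 over pairs) against 0.748 times in KOPN-8 (0.733 to 0.764). The deficit was thus smaller in the 697 clone, but the segments were chosen from the KOPN-8 data, which favours a larger deficit there. With 1 clone per line and the edit not checked, this comparison cannot set aside an effect of SETD2 loss. A lower copy number of these segments in the clone cannot be told apart from other causes: among the strongest 10000 peaks the share was 0.867 times that of the controls (0.834 to 0.903) and 1.01 times in the neighbouring parts, but chromosome X stood at 0.878 times and chromosome 4 at 0.906 times. An effect of SETD2 loss, in both lines or in KOPN-8 alone, was not tested apart from the clone, and DNA copy number was not measured here.

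The 697 clone had more calls on chromosome 19. A difference in list length does not account for it, since with equal lengths 11.3% of its regions were gained against 3.65% elsewhere. Gene density cannot be told apart from a change of the chromosome itself: 19 lay 2.73 residual SDs above the trend of the other 21 autosomes and 5.49 above that of the 20 without chromosome 22, which itself lay 5.50 above it, and its 24.6 genes per Mb put it outside the range of both trends. A higher copy number of the whole chromosome may contribute, and it too cannot be told apart. Each of its 10 Mb windows stood above the controls, from 1.17 to 1.88 times, but not alike, and how calls follow copy number was not measured here. SETD2 loss remains open and untested, and in the KOPN-8 clone the share of chromosome 19 was 1.03 times that of the controls.

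The 697 clone had almost no calls on chromosome Y. A filter of the authors that removed called peaks is set aside only up to 21155121, the end of the last Y peak in a knockout list. Up to there the peak numbers leave room for at most 15 on Y, against at least 118 control peaks on all of Y. Of the 103 lost regions, 77 lay before that peak. The other 26 lay beyond it, where removed peaks would leave no gap in the numbers. A filter applied before calling would leave no gap either and was not tested. A library of another line is set aside by similarity, 0.572 or more between 697 knockouts and controls and at most 0.425 between lines. A loss of Y from the clone is a candidate explanation: the knockout lists called 1 region of Y, the region that all 8 lists hold, of 158. DNA content was not measured here, and an effect of the edit on Y was not tested.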
